A study of Danio rerio with 4 samples.

How the data were processed

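Total RNA from zebrafish testes was labelled with Cy3 and hybridized to 1-colour Agilent arrays, 2 from control fish and 2 from fish kept in 20 µg/L MCLR. Per the file headers, the scanner files were made with Agilent Feature Extraction 11.0.1.1. Per the file headers, the processed signal is a linear intensity, background-subtracted and detrended within each array and not normalized between arrays, and the raw spot and local background values are intensity values (median pixel brightness); 0 or 1 marks per spot give whether it stood well above background, was saturated or was an outlier. The deposited value table holds log2 values with equal medians and quartiles between arrays, as quantile normalization gives; its tool is not stated, and its values correlated across probes with the log2 processed signal at 0.992 to 0.995. It was used only as an alternative.

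The log2 processed signal was reduced by the log2 of each array's 75th percentile over non-control spots, which was 393.3 and 310.2 on the control arrays and 301.0 and 397.8 on the MCLR arrays. Spots of 1 probe were averaged, and 60 probes with outlier marks were left out. Probes were named by their transcript identifiers through the gene name table of assembly GRCz12tu and a table of transcript names; this matched 25978 probes (59.6%) and 13373 genes, and the other probes were tested under their own names but not described. That assembly differs from the one the array was built on, so no coordinates are given. A probe was kept if it stood well above background on every array of at least 1 group, and a gene was represented by its probe with the highest mean level over the 4 arrays. This gave 24330 genes, of which 12496 had names. A gene counted as not above background where its probe failed that mark on both arrays of a group; its fold was then given as a lower bound, against the lowest signal that stood well above background on each array (6.83, 6.30, 8.43 and 8.19).

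MCLR was compared with control by limma 3.58.1 in R 4.3.3 (linear model with group only, moderated by eBayes, two-sided, Benjamini-Hochberg under 0.05 over all genes). With 2 residual degrees of freedom and 3.52 from the prior, a gene with the median standard error of 0.28 needed a log2 fold change of 0.69 for an unadjusted p of 0.05. Genes at least 2-fold different at an unadjusted p under 0.05 were counted as a description. A total of 30 gene lists of testis cell types, hormone and stress pathways, toxin targets and other tissues, each with at least 5 tested genes, were tested with camera at its preset correlation of 0.01 (two-sided, Benjamini-Hochberg over the 30 lists), with an estimated correlation, and with fry. Members were also counted after adjustment over the list alone. A list's median was the same with its undetected members at their bounds. Up to 4 members with the smallest p in each list were taken up for description. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each direction, up to 15 genes with a proper symbol and no overlap between the groups, first those past the adjusted threshold by fold, then those at least 2-fold different at an unadjusted p under 0.05 by p, and 21 genes of testis function in any case. Of these, odf3b is now named cimap1b and ppp2ca is ppp2caa. Eligible for the rule were 351 higher and 18 lower genes. Another 4 lists, of brain, clock, heat shock factor target and immediate early genes, were added after the data were seen and adjusted among themselves.

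The alternatives were quantile normalization, normexp background correction with an offset of 50 on the median raw intensity (the mean raw intensity is not in the files) then quantile normalization, scaling to each array's median, the deposited value table, no filter on dim probes, well above background on all 4 arrays, the mean of a gene's probes, every probe on its own, the replicate number as a block, a trended and robust prior, and leaving out each array in turn. Where 1 array remained in a group, it was assumed to vary like the other group. Restricting the genes to a mean level above -3 was added after the data were seen. A slide block was not run, since all arrays lay on 1 slide. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served to read the files and draw the plots.

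The fit was tested on simulated data in 20 runs with 24330 genes, the fitted means and spreads drawn from the fitted prior, in the comparison of 2 with 2 arrays. Of genes changed by 1, 2, 3 and 4 on the log2 scale (50 of each per run), 0.1%, 16.7%, 71.7% and 90.4% passed the adjusted threshold, and 47.4% of those changed by 1 passed the 2-fold threshold at an unadjusted p under 0.05. Unchanged genes had an unadjusted p under 0.05 in 5.00% of cases. Outside the genes changed by 1 to 4, a median of 495 per run passed the 2-fold threshold at that p. The 40 list genes shifted by 0.5 were eligible for this count. A list of 40 genes shifted by 0.5 was called in 20 of 20 runs, and 0 of the 30 other lists per run were called. The simulated genes varied independently, while the real lists had estimated correlations of up to 0.83. The runs therefore do not show how often camera calls correlated lists falsely.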

Results

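Gene expression was measured with 1-colour arrays in testes of 4-month-old zebrafish. The fish had spent 6 weeks either in water with 20 µg/L microcystin-LR (MCLR), a cyanobacterial toxin that blocks the protein phosphatases PP1 and PP2A, or in water without it (0 µg/L). Each group had 2 arrays. All 4 arrays lay on 1 slide, with the MCLR samples at positions 1 and 2 and the control samples at positions 3 and 4, so position and group cannot be told apart. Between 81.9% and 88.2% of the 43803 zebrafish spots of an array stood well above background, and 0 were saturated. The 75th percentile of signal was 262.6 and 221.3 times the median negative control on the control arrays, and 159.9 and 223.0 times on the MCLR arrays. The labels do not say whether the replicates were separate pools of fish, nor which arrays belong to which of the independent experiments that the study describes as holding both groups, so the arrays were not matched by number. The p-values below measure only the spread between these samples, and the number of arrays limits their precision.

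The comparison of MCLR with control asks which genes of the testis respond to the toxin. A pair of genes for the inducible heat shock protein Hsp70, a chaperone made under protein stress, stood apart among the well-detected genes. The level of hsp70l was 3.70 and 3.57 on the control arrays and 1.38 and 1.32 on the MCLR arrays, on a log2 scale relative to each array's 75th percentile. Its log2 fold change was -2.29 ± 0.23 (SE, n = 2 per group), 4.87-fold lower, and its 2 probes gave -2.27 and -2.29. The level of hsp70.3 was 2.23 and 1.95 in the controls and -0.09 and -0.26 in MCLR. Its log2 fold change was -2.26 ± 0.25, 4.80-fold lower, and its 3 probes gave values from -1.42 to -2.26. With limma, adjusted over all genes, p was 0.0605 for hsp70l and 0.0613 for hsp70.3, so neither passed the threshold of 0.05. Adjusted over the list alone, both passed within the endoplasmic reticulum and heat stress list, the smaller adjusted p being 4.45e-03. Both passed over all genes with median scaling (0.0149 and 0.0150), with a trended and robust prior (0.0236 and 0.0320) and without control replicate 2 (0.0402 and 0.0400), and hsp70l alone did without control replicate 1 (0.0486); over all settings the adjusted p ran from 0.0149 to 0.965 for hsp70l and from 0.0150 to 0.997 for hsp70.3.

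Across the 24330 genes tested, limma called 0 genes higher and 0 lower in MCLR after adjustment, with a smallest adjusted p of 0.0563. At an unadjusted p under 0.05, 2110 genes were higher and 129 lower, against 1216 in all expected by chance. At least 2-fold differences at that p numbered 1308 higher and 59 lower genes, so that 95.7% were higher in MCLR. The split moved with the scaling: 491 higher and 205 lower with quantile normalization, 1172 and 120 with median scaling, 350 and 177 in the deposited value table, and 11 and 14 after a background correction with an offset, which shrinks any fold of dim genes towards 0 whatever its cause. Without control replicate 2 it was 1884 and 701 (72.9% higher). Without one of the other arrays it was 1034 to 1534 higher and 128 to 163 lower. Adjusted calls appeared with median scaling (208 higher, 6 lower), without control replicate 1 (173 and 41), without control replicate 2 (240 and 88), and with the trended and robust prior, which called 2 lower genes, hsp70l and hsp70.3. Both arrays of one group lay above both of the other in 34.4% of genes, where chance gives 33.3%.

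Other named genes lower in MCLR reached 2-fold at an unadjusted p under 0.05 but not the adjusted threshold. Among them atp1a3b, a sodium pump subunit of nerve cells, had levels of 3.29 and 2.74 in the controls and 1.40 and 1.70 in MCLR, a log2 fold change of -1.47 ± 0.30 (adjusted p = 0.177). Genes of a brain list, chosen after the data were seen, were highest on control replicate 1 in 41 of 63 cases. The inward-rectifier potassium channel genes kcnj1a.1 and kcnj1a.2 had log2 fold changes of -1.07 and -1.09 (another probe of kcnj1a.2 gave -0.02), the calcium channel subunit gene cacna2d2b -1.35, and cyb561d2, for a cytochrome b561, -1.08. The log2 fold change of tagapb was -1.04. After the background correction the values were -0.69 for kcnj1a.1, -0.63 for kcnj1a.2, -0.44 for cacna2d2b, -0.32 for cyb561d2 and -0.34 for tagapb. The pancreatic elastase gene ela2 had -1.85, with 2.28 and 3.69 in the controls against 0.80 and 1.48 in MCLR. The transcription factor gene foxb1b was at least 1.34-fold lower, the small heat shock gene hspb3 at least 1.21-fold and hspa12a.3 at least 1.1-fold, since their MCLR signals did not stand above background; without a filter on dim probes another probe gave hspb3 a log2 fold change of 0.45 and hspa12a.3 one of 0.23. The lens crystallin gene crybb2 (-2.04), the clock gene nr1d2a (-1.15) and the lysosomal galactosidase gene gla (-1.15) each had probes of opposite sign.

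The 15 named genes with the smallest p among those higher in MCLR all lacked a signal well above background on both control arrays, so only bounds can be given. Taking the MCLR signal as RNA, they were at least 1.49-fold to 2.96-fold higher, with adjusted p from 0.0563 to 0.0613 (limma). They included the receptor genes chrm5a (acetylcholine, at least 2.59-fold), taar1b (trace amines, at least 2.83-fold), adrb2a (adrenaline, at least 1.54-fold), trhr2 (thyrotropin-releasing hormone, at least 1.49-fold), oxgr1a.1 (at least 1.64-fold) and gpr34l (at least 1.51-fold). The others were hoxd3a, a patterning gene (at least 2.96-fold), ccdc3a (2.92), fabp6, a bile acid binding protein (2.56), fbxo40.1 (1.90), tnnt2e, a troponin T (1.70), tmem119a (1.69), angptl6 (1.69), ceacam1 (1.64) and wnt5b, a secreted signal (1.57), each as a lower bound of the fold. After the background correction with an offset their log2 fold changes lay between 0.09 and 0.28. A background difference between the groups' arrays, which could not be told apart from a response, would lower the bounds given here.

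**Figure D1:**
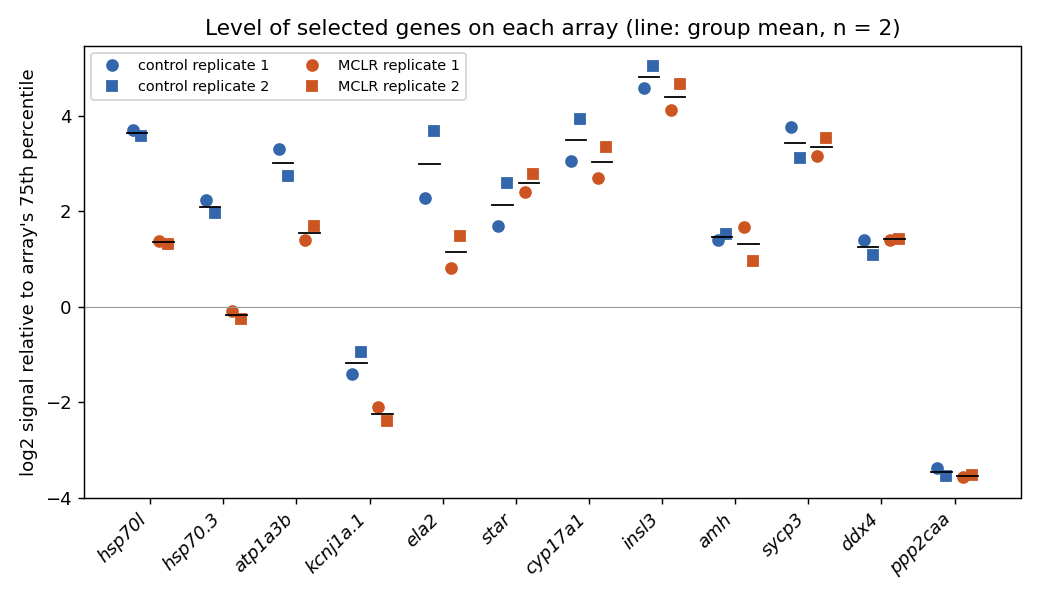
Log2 signal of 12 genes relative to each array's 75th percentile (vertical axis), with a point for each of the 4 arrays and a line for each group mean (n = 2). The points of hsp70l (3.70 and 3.57 against 1.38 and 1.32) and hsp70.3 (2.23 and 1.95 against -0.09 and -0.26) do not overlap between groups, while the points of insl3, amh and sycp3 do.

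Of 19 measured genes chosen in advance for testis function, toxin target or stress, 0 passed the adjusted threshold with limma, the smallest adjusted p being 0.79 for gsta.1, and 0 had an unadjusted p under 0.05. In the Leydig cell and steroid pathway, star, which brings cholesterol into mitochondria, had a log2 fold change of 0.45 ± 0.37, cyp17a1 of androgen synthesis -0.48 ± 0.40, and the hormone gene insl3 -0.41 ± 0.31. The receptor genes gave 0.75 ± 0.52 for fshr, with 0.21 on control replicate 1 against 1.70 on control replicate 2, 0.40 ± 0.29 for lhcgr and -0.0152 ± 0.31 for ar. The value of ar was positive in the deposited value table (0.03), after quantile normalization (0.03) and after the background correction (0.08). In Sertoli cells amh gave -0.14 ± 0.31, and the growth factor igf3 -0.20 ± 0.46. The aromatase cyp19a1a gave -0.09 ± 0.23. Among germ cell genes, ddx4 of the germ line gave 0.17 ± 0.25, the piRNA gene piwil1 -0.03 ± 0.24, the synaptonemal complex gene sycp3 -0.09 ± 0.32, the recombinase dmc1 0.32 ± 0.29 and the sperm tail gene cimap1b 0.02 ± 0.23. The value of cimap1b was -0.02 after quantile normalization, after the background correction and in the deposited value table. The target genes of the toxin gave 0.22 ± 0.29 (ppp1caa) and -0.08 ± 0.24 (ppp2caa), and the stress genes gave 0.41 ± 0.23 for gsta.1 and 0.16 ± 0.30 for hspa5. The 95% intervals of 7 of the 19 reached a 2-fold difference, up to a log2 fold change of 2.05 for fshr. Probes of opposite sign occurred for ppp2caa (-0.08 and 0.90), lhcgr (-0.36 and 0.40), cyp19a1a (-0.09 and 0.31), ar (-0.37 to 0.23) and piwil1 (-0.03 to 0.22), and the dim lhcgr gave 0.02 after the background correction. Steroid gene hsd3b1 and the egg yolk gene vtg1 carried no probe with a matching name.

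Of the 30 gene lists, camera with its preset correlation called 6, each against all other genes, whose log2 fold change averaged 0.17. With an estimated correlation none of the 6 held, each with an adjusted p of 0.94. A different test, fry, asks whether a list moves on balance at all and compares it with no other genes; it gave an adjusted p of 0.934 for each. No list had a member past the threshold over all genes. The exocrine and endocrine pancreas list was lower in MCLR (26 genes, median log2 fold change -1.94, adjusted p = 7.07e-10), with 25 of 26 members lower and 25 members highest on control replicate 2. The list shared 0 of its 28 genes on the array with another list, and 26 of 26 tested members stood well above background on each of the other 3 arrays. Examples were the elastase gene ela2l, at 1.91 and 5.38 in the controls and 1.67 and 1.55 in MCLR, the hormone gene sst1.1 at -2.83, 0.29, -2.71 and -4.56, and sycn.2 at -3.52, 1.49, -4.85 and -3.83. Without control replicate 2 its median was 0.27 and its adjusted p 0.656.

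The mitochondrial respiratory chain list was lower in MCLR (80 genes, median -0.11, adjusted p = 1.01e-05, and 0.94 with an estimated correlation), with 67 members lower, among them ndufb6 of complex I at -0.48 ± 0.24 and uqcrq of complex III at -0.36 ± 0.23. Without MCLR replicate 1 its median was -0.03 and its adjusted p 0.272, and without MCLR replicate 2 the median was -0.20. The list of PP1, PP2A, PP4 and PP6 phosphatase subunits was lower by camera (35 genes, 23 lower, median -0.08, adjusted p = 5.60e-03, and 0.94 with an estimated correlation). It covers more than PP1 and PP2A, which the toxin blocks, and included ppp2r5eb at -0.40 ± 0.25 and ppp2r1bb at -0.31 ± 0.23. The target genes ppp1caa and ppp2caa stood at 0.22 and -0.08 (another probe of ppp2caa gave 0.90). The call of this list ended with quantile normalization (0.258), in the deposited value table (0.245) and without control replicate 2 (median -0.06). Without control replicate 1 the median was -0.15. With the mean of a gene's probes the median was 0.01 while the list was still called lower (0.0254). The cell cycle and mitosis list was lower than all other genes by camera (71 genes, 47 lower, median -0.05, adjusted p = 0.0101, and 0.94 with an estimated correlation). In it mki67 stood at -0.41 ± 0.26 (5 probes, from -0.75 to 0.22) but the condensin gene ncapg at 0.68 ± 0.28 (0.28 with another probe). Its median level was 2.84 to 3.10 on the arrays. All genes above a mean level of 2 averaged a log2 fold change of -0.035, near the list's mean of -0.033. The list was not tested against genes of its level. Its call ended with quantile normalization (0.879), the background correction (0.757), the deposited value table (0.892), among genes above a mean level of -3 (0.287), and without control replicate 2 (0.174) or MCLR replicate 1 (0.846), where the median was 0.05.

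The endoplasmic reticulum and heat stress list was lower by camera (55 genes, adjusted p = 0.0129, and 0.94 with an estimated correlation), with a mean of -0.09 and a median of -0.0022. Its members with the smallest p were the 2 Hsp70 genes above, followed by ppp1r15a at -0.44 ± 0.23 and hspb8 at -0.46 ± 0.31. Its median was 0.04 with the mean of a gene's probes, where the call stood (adjusted p = 0.0243), and 0.03 in each of the quantile, background-corrected and deposited values, where the adjusted p was 0.750, 0.757 and 0.738. The call also ended among genes above a mean level of -3 (0.287), without control replicate 2 (0.188, median 0.09) and without MCLR replicate 1 (0.348, median 0.05). The immune cell list was the single list called higher in MCLR (47 genes, median 0.40, adjusted p = 0.0129, and 0.94 with an estimated correlation), with 42 members higher and 32 highest on MCLR replicate 2. Its members included irf1b, an interferon-regulated transcription factor (0.71 and 1.05 in the controls, 1.62 and 2.13 in MCLR), mfap4.1 (0.12, 0.52, 0.93 and 1.52) and the cytokine genes tnfa (log2 fold change 0.83 ± 0.30) and il6 (1.07 ± 0.32), both dim, with 0.24 and 0.13 after the background correction, where the list median was 0.19. The call ended with no filter on dim probes (0.0626), without control replicate 2 (median 0.34) and without MCLR replicate 2 (median 0.18). Without MCLR replicate 1 the median was 0.71, and without control replicate 1 it was 0.43.

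**Figure D2:**
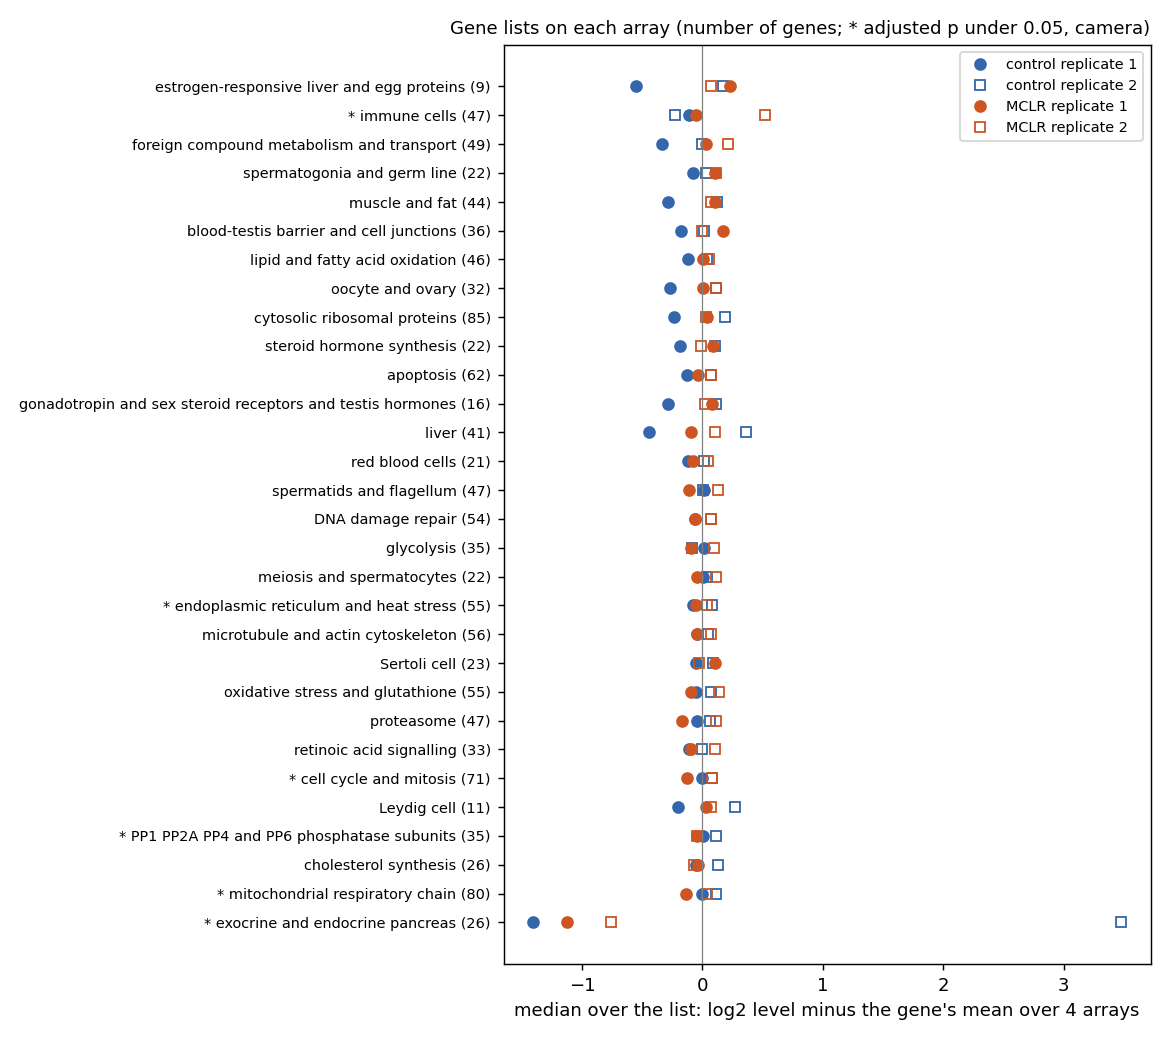
For each of the 30 gene lists (vertical axis, number of genes in brackets), the median over its genes of the log2 level minus the gene's mean over the 4 arrays (horizontal axis), with a point for each array. The pancreas list stands at 3.48 on control replicate 2 and between -1.41 and -0.76 on the other arrays, and the immune list at 0.52 on MCLR replicate 2.

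The other 24 lists were not called. Among germ cell lists, spermatogonia and germ line had a median of 0.17 (22 genes, adjusted p = 0.761), with pou5f3 at 0.99 ± 0.28 (0.66 after the background correction), meiosis and spermatocytes -0.0016 (22 genes, 0.402), and spermatids and flagellum 0.02 (47 genes, 0.164), with the sperm glycolysis gene gapdhs at -0.30 ± 0.24 (4 probes, from -0.50 to 0.05). Among somatic cell lists, Sertoli cell had -0.0052 (23 genes, 0.409), Leydig cell -0.06 (11 genes, 0.535) and blood-testis barrier and cell junctions 0.13 (36 genes, 0.813). In the last, 25 of 36 members were higher, among them the dim itgb1a at 1.15 ± 0.36 (0.14 after the background correction). The gap junction gene gja1b was lower, at -0.65 ± 0.31. The hormone lists gave 0.05 for steroid hormone synthesis (22 genes, 0.489), where hsd11b2 had -0.67 ± 0.31, 0.04 for gonadotropin and sex steroid receptors and testis hormones (16 genes, 0.947), and 0.42 for estrogen-responsive liver and egg proteins (9 genes, 0.361), where the dim vtg2 had 0.84 ± 0.36 (0.09 after the background correction). The median of estrogen-responsive liver and egg proteins was -0.06 without control replicate 1 and 0.81 without control replicate 2. The list was called higher in the latter (0.0493) and with the mean of a gene's probes (0.0480). Cholesterol synthesis had -0.08 (26 genes, 0.0654), retinoic acid signalling -0.03 (33 genes, 0.402), glycolysis -4.5e-04 (35 genes, 0.361), and lipid and fatty acid oxidation 0.08 (46 genes, 0.514). Cholesterol synthesis was called lower with the background correction (0.0408), no filter on dim probes (0.0265) and above a mean level of -3 (0.0423).

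Stress and damage lists gave -0.01 for oxidative stress and glutathione (55 genes, 0.164), where the metallothionein gene mt2 had -0.99 ± 0.52, 0.05 for apoptosis (62 genes, 0.608), 0.02 for DNA damage repair (54 genes, 0.152), and 0.22 for foreign compound metabolism and transport (49 genes, 0.104). In the last, ahrrb, the repressor of the aryl hydrocarbon receptor, had 1.11 ± 0.30 (0.71 after the background correction). The organic anion transporter slco3a1a was at least 1.88-fold higher if its MCLR signal is taken as RNA (log2 fold change 0.19 after that correction). The list of foreign compound metabolism and transport was called higher with the mean of a gene's probes (0.0376), without control replicate 2 (0.0493, median 0.45), without MCLR replicate 1 (0.0260) and among genes above a mean level of -3 (0.0263). Its median was 0.08 without control replicate 1. The proteasome list gave -0.02 (47 genes, 0.0512), cytosolic ribosomal proteins 0.05 (85 genes, 0.402), and microtubule and actin cytoskeleton -0.0040 (56 genes, 0.261), where msnb had 0.82 ± 0.28. The proteasome list was called lower with no filter on dim probes (0.0137) and the mean of a gene's probes (0.0376). Among lists of other tissues, liver gave 0.03 (41 genes, 0.402), red blood cells 0.03 (21 genes, 0.402), muscle and fat 0.15 (44 genes, 0.813), and oocyte and ovary 0.08 (32 genes, 0.928). Adjusted over the list alone, 2 members passed in foreign compound metabolism and transport (slco3a1a and cyp2aa7), 1 in lipid and fatty acid oxidation (fabp6) and 1 in oocyte and ovary (zp3a.2), and 0 over all genes. None of these members stood well above background on either control array. After the background correction their log2 fold changes were 0.19, 0.12, 0.28 and 0.17 in that order. The liver list was highest on control replicate 2 in 22 of 41 genes and the ribosomal list in 68 of 85; without that array the liver list was called higher (0.0135), and without control replicate 1 both were called lower (6.37e-07 and 1.31e-04). Without MCLR replicate 2, camera called 13 lists, among them proteasome (4.05e-06), spermatids and flagellum (3.00e-04) and oxidative stress and glutathione (1.22e-03), all lower.

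Camera's direction and a list's own values differed in sign in some of these lists, since the other genes averaged above 0. The direction was lower against a positive median in 9 lists, namely DNA damage repair, spermatids and flagellum, red blood cells, liver, cytosolic ribosomal proteins, steroid hormone synthesis, lipid and fatty acid oxidation, apoptosis, and gonadotropin and sex steroid receptors. It was lower against a positive mean in 14 lists: those same lists without red blood cells, and oxidative stress, microtubule and actin cytoskeleton, retinoic acid signalling, meiosis, Sertoli cell and Leydig cell. In these last 6 lists and in red blood cells, median and mean also differed in sign. With other scalings the list medians changed sign in 5 lists (quantile), 8 (background correction) and 6 (deposited table); the endoplasmic reticulum and heat stress list was the 1 called list among them.

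The higher genes lay at low signal. Of the 1308 genes at least 2-fold higher at an unadjusted p under 0.05, 1261 had a mean level at or below -3, and 660 had no control array well above background. Genes up to a mean level of -4 (4638 genes) had a mean log2 fold change of 0.68, those above 2 one of -0.04, and after the background correction the corresponding means were 0.02 and -0.0016. Among genes above a mean level of -3, a restriction chosen after the data were seen, 52 were higher and 30 lower. Correlations of levels across genes, which are not independent replicates, ran from 0.965 to 0.981 between arrays; the 2 control arrays gave 0.969, the 2 MCLR arrays 0.981, and control replicate 2 with MCLR replicate 2, of different groups, 0.979.

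**Figure D3:**
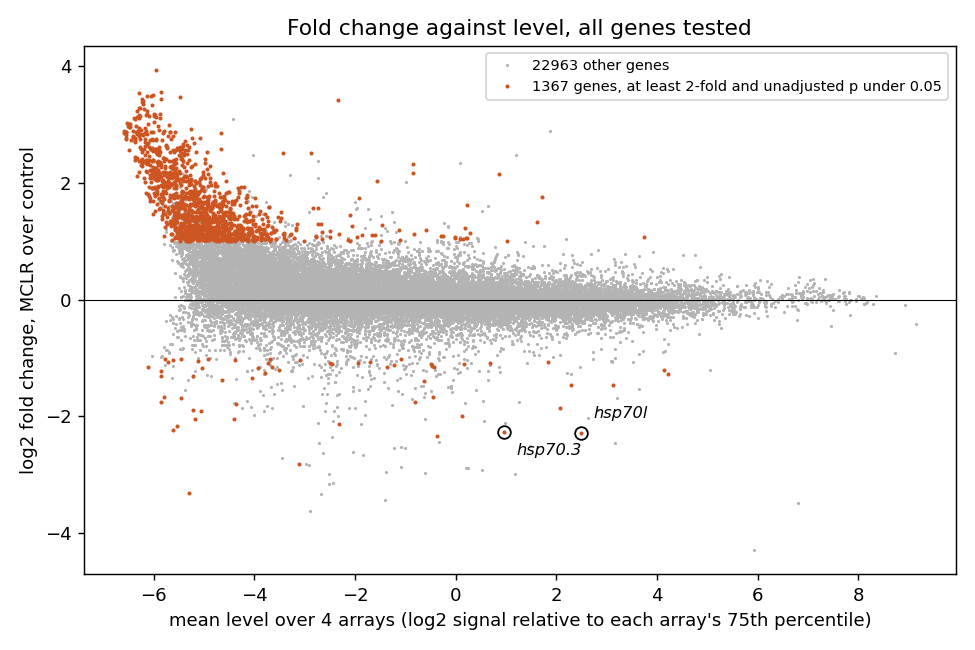
Log2 fold change of MCLR over control (vertical axis) against the mean log2 level over the 4 arrays (horizontal axis) for the 24330 genes tested, with the 1367 genes at least 2-fold different at an unadjusted p under 0.05 coloured. Most coloured points lie above 0 at the low end, with 1261 higher genes at or below a mean level of -3, and the circled points are hsp70l and hsp70.3.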

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

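The tests of a background difference, of a response in genes of all levels, of pancreatic tissue, of MCLR acting on pancreatic genes, and of the Hsp70 genes were chosen only after the results were seen, and the brain list test was prompted by brain genes already seen but uses other genes, whose values had not been seen.

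Control spots that match no zebrafish gene, the E1A probes, were brighter on the MCLR arrays, a signal in data the comparison did not use. Their median processed signal was 12.05 on MCLR replicate 1 and 8.02 on MCLR replicate 2, against 1.98 and 1.59 on the control arrays.

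The arrays can be split into 2 and 2 in 3 ways, which is too few for a share under 0.05. The real split gave 1367 genes at least 2-fold different at an unadjusted p under 0.05, the highest of the other splits 434, and 1 split, the real one, gave as many as 1367.

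The first pattern was the excess of dim genes higher in MCLR, 1261 of 1308 at a mean level at or below -3. A response of the testis in genes of all levels would raise bright genes too, but among genes above a mean level of -3 that differed at least 2-fold at an unadjusted p under 0.05, 63.4% were higher (95% exact interval 52.0% to 73.8%, taking genes as independent), against 95.7% of all genes. A background level that differed between the groups' arrays is a candidate explanation: 9 of 10 E1A probes were higher on both MCLR arrays. Over all 10 the mean difference was 1.79 on the log2 scale (SD 0.81), but over the 153 negative control spots it was 0.31. Raw medians on the control and MCLR arrays were 35, 33, 47 and 43.2 for E1A, 30, 29, 32 and 33 for the negative controls, and 29, 29, 33 and 33 for dark corner spots. A background difference and a response limited to dim genes cannot be told apart here, since the control spots moved by unequal amounts, position on the slide followed the groups and the sources do not say whether E1A targets were added to the samples.

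The second pattern was genes of other tissues high on some arrays and not on others. An effect of MCLR on pancreatic enzyme genes would set both MCLR arrays below both controls, but 11.5% of the 26 pancreas genes were so, and the list's median deviation from each gene's mean was lower on control replicate 1 (-1.41) than on the MCLR arrays (-1.13 and -0.76). Pancreatic tissue in control replicate 2 may account for the pancreas list, since 25 of 26 members were highest there, including ela2l at 5.38 against 1.91 or less elsewhere, and without that array the list median was 0.27. For brain tissue in the replicate 1 arrays, 81.0% of 63 brain genes not seen before were higher on control replicate 1 than on control replicate 2 and 71.4% higher on MCLR replicate 1 than on MCLR replicate 2. That lies between the bounds set in advance (75% in both groups for, under 60% in either against), so brain tissue on these arrays stays open, although the 31 control and 9 MCLR differences of at least 1 on the log2 scale all had replicate 1 higher.

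The third pattern was the lower level of hsp70l and hsp70.3 in MCLR. A background difference as its cause is argued against, since the E1A spots were higher and not lower in MCLR, and 95.7% and 89.7% of the log2 differences were left after the background correction with an offset (-2.19 and -2.03). A lower heat shock response as a whole is argued against by the other 33 heat shock factor targets. Their median log2 fold change was 0.004 with 16 of 33 lower, although hspb8 (-0.46) and hsp90aa1.2 (-0.34, with another probe at 0.08) lay below 0. Of this list's 35 genes on the array, 18 also belonged to another list. The test was therefore not fully independent of list results already seen. The log2 fold changes of hsp70l and hsp70.3 differed by 0.023 (SE 0.34). Whether 1 signal was counted in near-identical copies or 2 genes were lowered alike cannot be told without probe sequences. A response of these genes to MCLR stays open, as does a difference in handling, for which the immediate early and handling stress list was not called (adjusted p = 0.598).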

How the results depend on the processing

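Only the restriction to genes above a mean level of -3 was chosen after the results were seen. No named gene passed the adjusted threshold, so staying below it says nothing of stability. Of 2813 values of 195 named genes, 2751 drew no change of call, 60 passed the threshold (19 with median scaling, 2 with the trended and robust prior, 18 without control replicate 1, 21 without control replicate 2) and 2 reversed, hspa12a.3 (0.23) and hspb3 (0.45), both with no filter on dim probes, where a different probe was read. Of 360 values of the 24 uncalled lists, 338 stayed uncalled (76 with a changed direction of the list test) and 21 became calls. The liver list reversed without control replicate 2 (median 0.42). Counted apart from these directions, 10 of the 30 list medians changed sign with median scaling, which shifts every gene alike. The cause of the changes below was not tested unless stated.

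Adjusted calls numbered 208 higher and 6 lower with median scaling, and 2 lower with the trended and robust prior. Leaving out an array gave 0 to 240 higher and 0 to 88 lower; of the called genes 210 of 214 with median scaling, 180 of 214 without control replicate 1 and 261 of 328 without control replicate 2 had a mean level at or below -3. At least 2-fold differences numbered 491 higher and 205 lower with quantile normalization, 11 and 14 with normexp, 350 and 177 in the deposited table, 369 and 39 with all 4 arrays above background, 1999 and 91 for every probe (more tested) and 52 and 30 above a mean level of -3 (fewer tested). There were 2388 higher with no filter (more tested), 120 lower with median scaling and 115 lower with the replicate block. Leaving out an array gave 1034 to 1884 higher and 128 to 701 lower.

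Camera called 3 lists with quantile normalization, 3 in the deposited table, 13 without MCLR replicate 2, and 0 with an estimated correlation (adjusted p = 0.94 for all 6 called lists); fry, which tests each list against no change, called 0 (0.934 for all 6). The lists' other lost calls had these adjusted p values. Cell cycle had 0.879 with quantile normalization, 0.757 with normexp, 0.892 in the deposited table and 0.287 above a mean level of -3. Endoplasmic reticulum and heat stress had 0.750, 0.757, 0.738 and 0.287 in the same settings. The phosphatase list had 0.258 with quantile normalization and 0.245 in the deposited table, and the immune list 0.0626 with no filter. Leaving out an array moved the adjusted p from 7.27e-06 to 0.846 for cell cycle, 1.98e-03 to 0.348 for endoplasmic reticulum and heat stress, 7.93e-60 to 0.656 for pancreas (reversed without control replicate 2), 1.95e-06 to 0.867 for immune cells, 1.22e-08 to 0.272 for the respiratory chain, 8.34e-03 to 0.123 for the phosphatases and 6.37e-07 to 0.846 for liver.

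The lowest correlation between arrays across genes moved from 0.965 to 0.978 with normexp, 0.958 with the mean of a gene's probes and 0.956 above a mean level of -3. Signal over background limits the dim genes, since 951 of the 1308 higher genes fell short of well above background on at least 1 control array.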

Other observations

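The brain, heat shock target and immediate early lists, the genes above a mean level of -3 and the single genes named here were chosen only after results were seen; the clock list test was written before its values were seen.

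Among genes above a mean level of -3, those at least 2-fold higher in MCLR at an unadjusted p under 0.05 included s1pr4, a sphingosine phosphate receptor of leukocytes (log2 fold change 2.04), the chemokine gene cxcl18b (1.26), gig2g (1.57), samsn1b (1.57) and blk, a kinase of B cells (1.03). Except for blk, these were higher on MCLR replicate 2 than on MCLR replicate 1, at 0.17 against -1.26 for s1pr4, -1.07 against -1.78 for cxcl18b, -1.41 against -2.49 for gig2g and -1.37 against -2.74 for samsn1b. The others included gch1 (1.18) and dct (1.13), enzymes of pigment synthesis, timp2b, a protease inhibitor (1.62, with levels of 0.27 and 1.82 on the MCLR arrays), gfra2a, a receptor subunit for neurotrophic factors (1.05), and cfap300 of cilia (1.00). After the background correction with an offset the values were 1.24 for s1pr4, 0.65 for cxcl18b, 0.71 for gig2g, 0.58 for samsn1b, 0.72 for blk, 0.54 for gch1 and 0.80 for dct. Lower genes included the nerve cell gene elavl4 (-1.09) and the haemoglobin gene hbba2 (-2.12, and -1.11 after that correction), with -4.54 and -2.20 on the MCLR arrays. The 3 probes of hbba2 gave -2.12 to -0.51. Of the 21 red blood cell genes 11 were higher, among them the haemoglobin gene hbae1.1 (0.82, and 0.43 after that correction). The smallest adjusted p over the 16456 genes above a mean level of -3 was 0.544, shared by hsp70l and hsp70.3, so none of these passed with limma. At an unadjusted p under 0.05, 296 of the 16456 were higher and 102 lower, together fewer than the 5% that chance gives.

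Several brain genes were higher on the replicate 1 array than on the replicate 2 array of each group. The level of the ependymin gene epd was 3.48 and -4.97 on the control arrays and -0.40 and -6.31 on the MCLR arrays, that of the glutamate transporter slc1a2b 4.07, -3.70, 1.75 and -3.80, that of the synaptic gene snap25a 4.26, -1.42, 1.17 and -1.81, and that of the brain aromatase cyp19a1b -0.02, -5.33, 1.35 and -4.57. Between replicates 1 and 2, 39 genes differed by more than 2 on the log2 scale in the same direction in both groups and 7 in opposite directions. The added brain list was lower in MCLR by camera (63 genes, median -0.21, adjusted p over the 4 added lists 7.41e-05, and 0.482 with an estimated correlation). The clock list was lower (34 genes, median -0.07, adjusted p = 1.51e-03, and 0.482 with an estimated correlation), but its median deviation from each gene's mean was 0.15 on control replicate 1, where 15 members were highest, and -0.11 on control replicate 2, against -0.09 and -0.11 on the MCLR arrays. Heat shock factor targets without Hsp70 were not called (33 genes, median 0.0040, 0.122), nor were immediate early and handling stress genes (38 genes, median 0.06, 0.598), where klf4 had 1.09 (0.20 after that correction) and fkbp5, a cortisol target, -0.64.

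A difference in time of day at sampling was tested as an explanation for the lower Hsp70 genes, since clock genes cycle over the day. Of the 34 clock genes, 5.9% differed by at least 1 on the log2 scale (95% exact interval up to 19.7%, taking genes as independent), below the bound set in advance. Of 5 genes named in advance only nr1d2a did so (-1.15, with another probe at 0.54). This argues against a difference in time of day that moves clock genes by at least 1. A smaller one was not tested and stays open. Of the other members with the smallest p, bhlhe41 was lower (-0.78, and -0.45 after the background correction). The genes bmal2 (0.75) and clockb (0.81, with another probe at -0.04) were higher, but with 0.13 and 0.06 after that correction. A list median does not show members that move in opposite directions.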
